A study of Homo sapiens with 499 samples.

How the data were processed

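Established tumour cell lines of the NCI-60 panel were measured on Affymetrix expression arrays after exposure to cisplatin or to vehicle. Per the labels' protocols, the lines grew in RPMI-1640 medium, were plated 24 h before treatment, received the compound in DMSO at a final 0.25 percent, and gave total RNA with an RNA quality score above 7.5 that was biotin-labelled with an Affymetrix HT One-Cycle kit. The 0 nM arrays carry the same treatment protocol as the others and were taken as the vehicle controls. The labels gave the line, dose, time and tissue of every array, and 499 arrays of 56 lines in 9 tissues fell into 9 groups of dose and time. Of these lines 53 had all 9 arrays. The 2 h arrays of U251, the 3000 nM array of PC-3 at 2 h and the 15000 nM array of SF-268 at 24 h were not analysed here.

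The values used were the deposited log2 values of 22277 probe sets, 1 column per array, and 0 columns of values were left unused. Per the labels, no summary or normalization method was named, and these steps are not given in the sources used here. The log base is also not given in the sources used here and was taken as log2 from the values, which ran from 2.82 to 14.26. If the base were another, every change would be scaled by 1 constant, which would alter counts by size of change and no adjusted p. Array medians lay between 5.23 and 5.70 and upper quartiles between 7.98 and 8.49, so the arrays were on a similar scale as deposited, and no further scaling was applied in the main setting. A scaling of this kind hides any change that all genes share. Signals near the background compress differences, so changes of dim genes are understated, and the number of arrays limits the precision. No pair of arrays held identical values (0 pairs).

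Probe sets were named through the platform annotation given, dated 2016, in which 19070 had exactly 1 gene symbol, 1043 several and 2164 none. Of the first, 19058 matched an NCBI gene identifier in the RefSeq table, and 0 symbols needed updating. Affymetrix control probe sets (62) were left out of the tests and used as controls of RNA integrity, hybridisation and labelling. For each gene the probe set with the highest mean over all arrays was kept, which left 11963 genes, 4310 of which had more than 1 probe set. No genome or gene lengths were given, so no coordinates are printed.

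The lines were the replicates, and arrays of the same line were paired. The pairing came from the line named in the labels and was checked in the data. Deviations from the group means correlated at 0.701 or more (median 0.948) between arrays of the same line, and at a median of -0.0448 (highest 0.814) between different lines. Nothing in the labels says that arrays came from separate cultures, so p-values measure only the spread between these lines. The labels named no batch or scan date.

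Each comparison used only the lines with all arrays concerned. Each line's log2 change was fitted with limma (lmFit and eBayes, default prior, version 3.58.1, in R 4.3.3) and tested against 0, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The number of genes with a mean change of at least 0.5 was counted as well. Differences of the change between times were tested on each line's difference of changes, differences between tissues with limma's moderated F test across 9 tissue labels, and leukemia lines against all other lines with limma. Tests of a direction were two-sided. The comparisons, tests, gene lists, alternatives and the rule for the genes to be named were fixed before the data were examined, except where a later choice is stated.

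The rule named, for 15000 nM against 0 nM at 24 h and at 6 h, the 10 largest mean rises and the 10 largest mean falls past the threshold with that sign in at least 75 percent of lines. It named 3 each way for every other comparison, 5 genes with the smallest p for the F test, and 3 each way for leukemia. For each gene list it named up to 4 members with the largest change past the threshold, or else the 1 with the smallest p.

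There were 22 gene lists: p53 targets, immediate early genes, ATF4 and unfolded protein response, histone genes, mitotic genes, S phase and DNA replication genes, nucleotide excision repair, Fanconi and homologous recombination, metallothioneins, NRF2 targets, platinum and copper transport, NF-kB targets, interferon-stimulated genes, heat shock, cholesterol synthesis, BCL2 family, ribosome biogenesis, and markers of epithelial, mesenchymal, melanocyte, blood and colon cells. Some genes are in several lists, for example PMAIP1 among p53 targets and the BCL2 family and XPC among p53 targets and excision repair. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over 22 lists within a comparison. Members were counted after adjustment over all genes and over the list alone. A score per line was the mean change of the measured members, compared between tissues by permuting tissue labels (100000 resamples), with adjustment over 22 lists. The number of genes moved by more than 1 per line was compared between tissues in the same way on ranks, which was added after the data were seen. These tissue tests were repeated without OVCAR-3 and with the change of the ACTB 3' to 5' difference as covariate, permuting residuals, also after the data were seen.

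Relations across lines were given as Pearson's r and Spearman's rho with permutation p-values, within clusters found by a Gaussian mixture model (mclust 6.1.1), and exact permutation was used below 10 lines. The overlap of the doses, which share 0 nM arrays, was set against 100 simulated draws of unchanged groups sharing those arrays, against independent lists, and against 20 splits of the 0 nM lines between the doses. Array controls were compared within lines by sign-flip permutation and adjusted over all such tests. Tables were handled with the R package data.table (1.17.8), Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

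The fits were tested on simulated data for 11963 genes with known changes. For 15000 nM against 0 nM at 24 h, 31.1 percent of true changes of 0.1, 90.7 percent of 0.25, 98.0 percent of 0.5 and 100 percent of 1 were recovered, with 14 false calls. At 6 h the shares were 54.8 percent for 0.1 and 100 percent for the larger changes (2 false calls), and at 2 h 52.8 and 100 percent (13 false calls). The F test recovered 24.0 percent of true changes of 0.5 and 84.4 percent of 1, and the leukemia test 48.0 and 95.9 percent. Of 22 lists 0 were called on simulated noise. This noise was drawn for each gene on its own, so it does not show how camera behaves when list members are correlated.

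The alternatives were subtraction of each array's median, quantile normalization, only genes above the median gene, the mean of all probe sets, all probe sets, leaving out NCI-ADR-RES, MDA-MB-435 and SNB-19 (reported to share an origin with OVCAR-8, M14 and U251), only lines with all 9 arrays, leaving out each tissue, no cell line block, a Wilcoxon signed-rank test, all arrays in 1 fit, and leaving out each leukemia and prostate line. Analyses without HCC-2998, OVCAR-3 or MALME-3M, and without OVCAR-3, A549 and T-47D at 6 h, were added after the data were seen.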

Results

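Gene expression was measured on Affymetrix arrays in 56 human tumour cell lines of the NCI-60 panel, a set of established lines used to profile anticancer drugs. Each line was exposed to cisplatin, a platinum compound that crosslinks DNA, at 3000 or 15000 nM, or to the vehicle at 0 nM, for 2, 6 or 24 h. The aim stated for the series was to set the responses of these lines side by side over time. Of 499 arrays, 56, 55 and 56 belonged to 0 nM at 24, 2 and 6 h, 56, 54 and 56 to 3000 nM at the same times, and 55, 55 and 56 to 15000 nM. The labels gave 8 lung, 8 melanoma, 7 renal, 7 colon, 7 ovarian, 6 breast, 6 CNS, 5 leukemia and 2 prostate lines. Each line had at most 1 array per dose and time, and 53 lines had all 9, so the lines were the replicates and each change was taken within a line. Nothing in the labels said that an exposure was repeated in a second culture of the same line, so the p-values measure the spread between lines. Array medians lay between 5.23 and 5.70 on the log2 scale, and the number of arrays limits the precision.

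Markers of melanocytes, blood cells and colon followed the tissue labels on average, while single lines and the other tissues were not checked with markers of their own. At 0 nM and 24 h the measured melanocyte markers averaged 10.08 ± 2.41 (SD, n = 8) in melanoma lines and 4.80 or less in every other tissue. Blood cell markers averaged 9.27 ± 1.05 (SD, n = 5) in leukemia lines, and colon markers 6.37 ± 1.65 (SD, n = 7) in colon lines, against 4.72 and 4.51 or less elsewhere. Epithelial markers were highest in colon lines at 10.45 ± 0.50 (SD, n = 7) and mesenchymal markers in CNS lines at 10.30 ± 1.40 (SD, n = 6).

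After 24 h at 15000 nM, ATF3 and CDKN1A rose in nearly every line while a set of single genes fell deeply. ATF3, a transcription factor of the stress response, rose by 2.51 ± 1.56 (SD, n = 55) on the log2 scale and was higher in 53 of 55 lines (limma adjusted p = 1.1e-15). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 1.68 ± 0.99 and was higher in 55 of 55 lines. GMDS, an enzyme of GDP-fucose synthesis, fell by 2.56 ± 1.14 (limma adjusted p = 7.55e-21), and SMYD3, a lysine methyltransferase, fell by 2.51 ± 1.16 in 55 of 55 lines. In all, 5819 of 11963 genes changed at adjusted p below 0.05, 3323 higher and 2496 lower. A mean change of at least 0.5 was reached by 564 of them, 208 higher and 356 lower.

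Other large rises were those of CXCL8, a neutrophil chemokine, at 1.62, the cytokine GDF15 at 1.34, and HBEGF, a ligand of the EGF receptor, at 1.27. TP53I3, PPP1R15A, MAFF, GADD45A and PMAIP1 rose by 1.24, 1.24, 1.23, 1.20 and 1.19. DPYD, which starts the breakdown of pyrimidines, fell by 2.26 ± 1.75, VPS13B fell by 2.23 and the SNARE protein gene STX8 fell by 2.14. FARS2, AGAP1 and DIAPH2 were lower at -1.93, -1.91 and -1.90, TBC1D5 at -1.84, and WWOX, which spans a common fragile site, at -1.82. STX8 and TBC1D5 were lower in 55 of 55 lines, and each of the other 8 of these 10 falling genes in at least 50.

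Listed targets of the tumour suppressor p53 rose together at 15000 nM and 24 h. Of 22 measured p53 targets, 20 rose, 0 fell and 2 did not pass, with 20 rising when adjusted over the list alone. DDB2, a damage recognition factor, rose by 0.85, and FAS and PPM1D by 0.85 and 0.86, values picked after they were seen. Of 17 immediate early genes, which respond within minutes to stimulation, 15 rose and 0 fell, and 16 rose when adjusted over the list alone. DUSP1 rose by 0.98 and KLF4 by 0.89. The preset-correlation camera test placed both lists above other genes (adjusted p = 2.29e-09 and 5.64e-07), but neither call held with an estimated correlation, which gave adjusted p = 0.204 for p53 targets and adjusted p = 0.194 for immediate early genes. Fry, which asks whether the members changed and not whether they changed more than other genes, called both higher (adjusted p = 7.15e-11 and 2.58e-12). At this dose and time fry called 18 lists, including all 13 that camera called.

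Inflammatory and antiviral genes were also higher at 15000 nM and 24 h. Of 16 NF-kB targets 14 rose, 0 fell and 2 did not pass, 14 rising when adjusted over the list alone. TNFAIP3, a feedback inhibitor of NF-kB, rose by 0.96 and CXCL2 by 0.66. Of 16 interferon-stimulated genes 14 rose and 0 fell, with 14 rising when adjusted over the list alone, among them IRF7 by 0.82, ISG15 by 0.81 and IRF1 by 0.79. Among 17 genes of the ATF4 and unfolded protein response, 10 rose and 2 fell, and 11 rose and 2 fell when adjusted over the list alone. DDIT3, which encodes CHOP, rose by 1.16 and CHAC1 by 0.70. The falls were those of HSPA5, the main chaperone of the endoplasmic reticulum, at -0.30, and VLDLR, a lipoprotein receptor, at -0.24. Camera called the 3 lists higher (adjusted p = 5.65e-05, 5.29e-07 and 0.0172). With an estimated correlation none was called, at adjusted p = 0.204 for NF-kB targets, adjusted p = 0.123 for interferon-stimulated genes and adjusted p = 0.394 for the ATF4 list.

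Mitotic genes fell at 24 h while genes of the G1/S transition and DNA replication rose. Of 25 mitotic genes, 19 fell, 1 rose and 5 did not pass, the same counts when adjusted over the list alone. The mitotic kinase PLK1 fell by 1.07 and was lower in 55 of 55 lines, and the kinesins CENPE and KIF20A and the checkpoint factor CDC20 were lower at -0.79, -0.75 and -0.66. The member that rose was CDK1, at 0.16. Of 25 S phase and DNA replication genes 18 rose, 3 fell and 4 did not pass, the same when adjusted over the list alone. Cyclin E genes CCNE2 and CCNE1 rose by 0.81 and 0.72, and CDC6, which loads the replicative helicase, by 0.68, whereas the helicase subunit MCM6 fell by 0.36. Of 10 histone genes 6 fell and 0 rose, also when adjusted over the list alone, led by H2AC6 at -0.98. Camera adjusted p was 2.24e-10 for mitotic genes, 0.000490 for S phase genes and 0.0141 for histone genes. With an estimated correlation these became adjusted p = 0.204, adjusted p = 0.432 and adjusted p = 0.362.

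More DNA repair genes rose than fell at 15000 nM and 24 h. Of 19 nucleotide excision repair genes, whose products remove bulky adducts, 10 rose and 3 fell, and of 18 Fanconi and homologous recombination genes 13 rose and 3 fell, the same counts when adjusted over each list alone. XPC rose by 0.56 and ERCC6 by 0.35, while RAD23B fell by 0.23. The nuclease gene EXO1 rose by 0.77, RAD51C by 0.44 and FANCG by 0.43, while FANCF and FANCC were lower at -0.28 and -0.27. In the BCL2 family 8 of 12 members rose and 1 fell, also when adjusted over the list alone. PMAIP1, BIK and BCL2L11, which promote cell death, rose by 1.19, 0.51 and 0.40. MCL1, which opposes cell death, rose by 0.21, and BCL2, which also opposes it, fell by 0.59. Camera called these lists higher at adjusted p = 0.0314, 0.00888 and 0.0172. With an estimated correlation each call was lost, at adjusted p = 0.123 for excision repair, adjusted p = 0.362 for the Fanconi list and adjusted p = 0.123 for the BCL2 family.

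Metal-binding and sterol genes fell at 15000 nM and 24 h. Of 8 metallothioneins, small proteins that bind heavy metals, 6 fell and 0 rose, also when adjusted over the list alone, with MT1F at -0.25 and MT1X at -0.20. Of 11 cholesterol synthesis genes 7 fell and 0 rose, also when adjusted over the list alone, with INSIG1 at -0.65 and LSS at -0.47. Camera adjusted p was 0.0314 and 0.0039, and with an estimated correlation adjusted p = 0.362 for each list. Of 11 platinum and copper transport genes 5 fell and 3 rose, or 5 and 4 when adjusted over the list alone. The efflux pump genes ABCC4 and ABCC1 were lower at -1.03 and -0.52 and the copper pump gene ATP7A at -0.37, while SLC31A2 rose by 0.35, and the list was not called (camera adjusted p = 0.204).

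The remaining 8 lists were not called at 15000 nM and 24 h. NRF2 targets had 8 risen and 2 fallen members of 16, or 10 and 2 when adjusted over the list alone, with OSGIN1 at 0.42 and the pentose phosphate enzyme TKT at -0.35 (camera adjusted p = 0.159). Heat shock genes had 4 risen and 1 fallen of 9, or 5 and 1 when adjusted over the list alone, led by HSPA4L at 0.55 (camera adjusted p = 0.206). Ribosome biogenesis had 3 risen and 2 fallen of 10, with NOP2 at 0.29 (camera adjusted p = 0.893). Of mesenchymal markers 3 of 9 fell, led by the cadherin gene CDH2 at -0.44 (camera adjusted p = 0.159). Epithelial markers had 3 risen and 1 fallen of 8, KRT18 at 0.22 and CDH1 at -0.20 (camera adjusted p = 0.914). Blood cell markers had 2 risen of 7, CORO1A at 0.32 (camera adjusted p = 0.431), or 1 when adjusted over the list alone. None of the 6 melanocyte or 6 colon markers passed (camera adjusted p = 0.532 and 0.910), and neither TYR at -0.12 nor LGALS4 at 0.05 did. Except for blood cell markers, these marker and ribosome counts were the same when adjusted over each list alone. Over all 132 list tests against 0 nM, the median, mean and test differed in sign in 15, none of which was called.

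**Figure D1:**
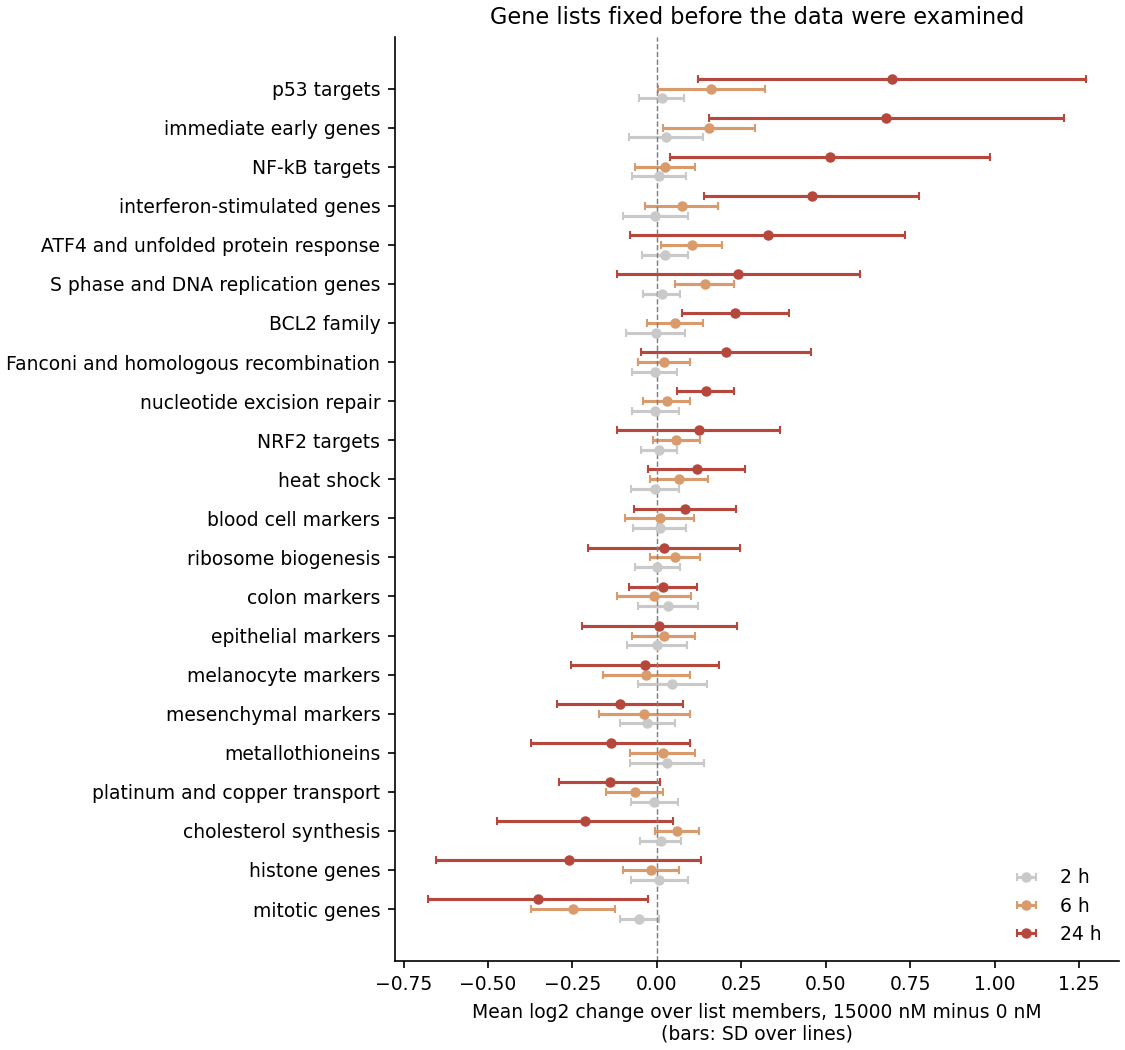
The horizontal axis gives the log2 change at 15000 nM minus 0 nM averaged over the members of each of 22 gene lists, and points and bars show the mean and SD over lines at 2, 6 and 24 h. At 24 h p53 targets averaged 0.70 and mitotic genes -0.35, and at 2 h p53 targets averaged 0.01 and mitotic genes -0.05.

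Array controls moved with this condition as well. The difference between 3' and 5' probe sets of ACTB, a measure of RNA integrity, was 0.21 ± 0.70 (SD, n = 55) higher at 15000 nM than at 0 nM after 24 h, and higher in 44 of 55 lines (sign-flip permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted 0.00024). The largest change was in OVCAR-3, and without that line it was 0.12 ± 0.16 (SD, n = 54, permutation p = 1e-05). The same measure of GAPDH differed by 0.04 ± 0.25 (permutation p = 0.367). Without the cell line as a block the count of changed genes was 1056 in place of 5819, and the calls of 13 lists became 10.

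At 3000 nM the 24 h response was smaller, with CDKN1A, ATF3 and WWOX again among the largest changes and with falling histone genes. CDKN1A rose by 0.50 ± 0.54 (SD, n = 56; limma adjusted p = 1.72e-07) in 49 of 56 lines, GINS4, of the replicative helicase, by 0.45 and ATF3 by 0.41. WWOX fell by 0.68 ± 0.61 (limma adjusted p = 1.64e-09) and was lower in 51 of 56 lines, DHRS2 was lower at -0.64 and H2AC6 at -0.52, each in 51 of 56 lines, whereas GMDS and SMYD3, which fell most at 15000 nM, were at -0.32 and -0.28. Of the histone genes 9 of 10 fell and 0 rose, also when adjusted over the list alone, with H1-2 at -0.40 and H2BC6 at -0.35. Of the mitotic genes 17 of 25 fell and 1 rose, or 18 and 1 when adjusted over the list alone, with PLK1 at -0.50 and CENPE at -0.37. Of the p53 targets 16 of 22 rose and 0 fell, or 20 and 0 when adjusted over the list alone, including DDB2 at 0.36 and FAS at 0.35. Fanconi and homologous recombination genes rose in 12 of 18 cases and fell in 1, or 14 and 1 when adjusted over the list alone, led by EXO1 at 0.33 and BLM at 0.26. Of 16 interferon-stimulated genes 8 rose, or 12 when adjusted over the list alone, including OAS3 at 0.23. Of 25 S phase and DNA replication genes 16 rose and 1 fell, or 17 and 3 when adjusted over the list alone, with CDT1 at 0.25.

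Altogether 1298 genes changed at 3000 nM and 24 h, 864 higher and 434 lower, and 4 changed by at least 0.5. Labelling controls were also lower in this comparison, at -0.12 ± 0.26 (SD, n = 56; sign-flip permutation p = 0.00039, adjusted 0.00468). Camera called 12 of 22 lists. The calls of 6 lists held with an estimated correlation, with adjusted p = 2.98e-06 for histone genes, 0.00388 for interferon-stimulated genes, 0.0112 for the Fanconi list, 0.0208 for p53 targets, 0.0251 for mitotic genes and 0.0352 for excision repair genes. Of the 19 excision repair genes 6 rose and 1 fell, also when adjusted over the list alone, with LIG1 at 0.20. The call of S phase genes was lost at adjusted p = 0.137 with an estimated correlation.

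The other 5 lists called at 3000 nM and 24 h had few members past the threshold and lost their call with an estimated correlation. Of 12 BCL2 family genes 5 rose and 0 fell, also when adjusted over the list alone, with PMAIP1 at 0.26 (adjusted p = 0.0511 with an estimated correlation). Of 10 ribosome biogenesis genes 3 fell and 0 rose, or 4 and 0 when adjusted over the list alone, with NOP16 at -0.11 (adjusted p = 0.0909 with an estimated correlation). Of 16 NF-kB targets 2 rose, CXCL8 at 0.19 and NFKB2 at 0.16, or 5 when adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). Of 8 metallothioneins 2 fell, MT1F and MT1H at -0.11 and -0.10, or 3 when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). In the ATF4 list 4 of 17 rose, also when adjusted over the list alone, with CHAC1 at 0.19 (adjusted p = 0.369 with an estimated correlation). Subtracting each array's median turned the split of higher and lower genes to 436 and 1126, and quantile normalization to 679 and 626. Without the cell line as a block limma called 0 genes, with 66 at unadjusted p below 0.05 against 2731 with it, and 316 passed with all arrays in 1 fit.

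The changes at 3000 and 15000 nM after 24 h shared genes and direction. In 55 lines with all 3 arrays, 702 genes were higher at both doses and 332 lower at both, against 236 and 89 for independent lists of the same sizes, and 37 changed in opposite directions. With each array's median subtracted only 436 genes in all were higher at 3000 nM and 24 h, so the 702 depends on the scale of the arrays. The independent lists take no account of the shared 0 nM arrays. Across genes, which are not independent replicates, the mean changes correlated at 0.60. Simulated unchanged groups sharing the same 0 nM arrays gave 0.50, a value set by their equal spread and shared arrays. The covariance was 0.00804 against 0.000440 in the simulation. With the 0 nM lines split between the doses, the medians were 231 and 109 shared genes, a correlation of 0.499 and a covariance of 0.00742. In these splits the doses shared no 0 nM array, so the correlation of 0.499 is not to be set against the simulated 0.50. Each dose then had fewer lines, and no expected overlap was computed for these shorter lists, so their counts cannot be set against 236 and 89.

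**Figure D2:**
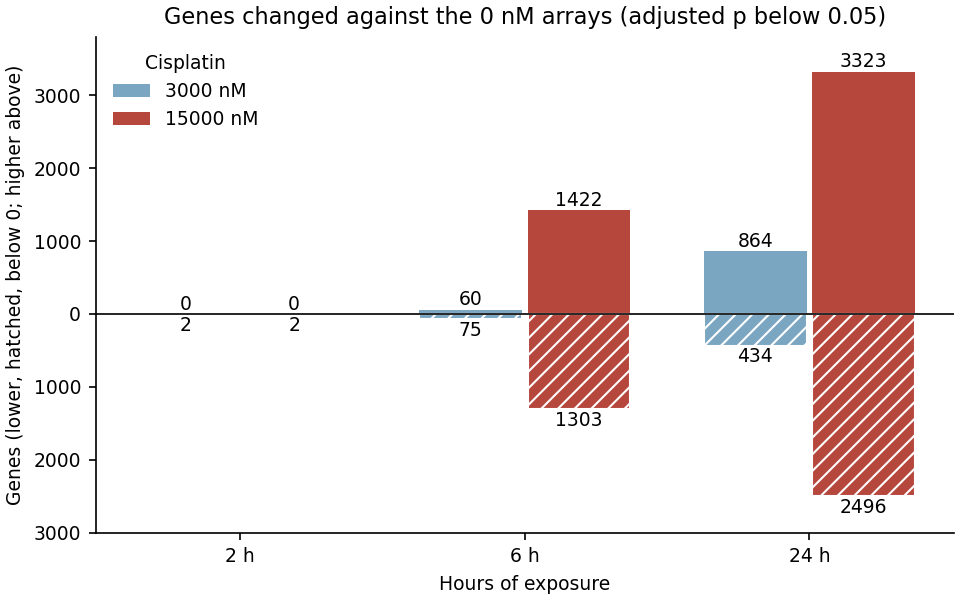
Bars give the number of genes that were higher (above 0) or lower (hatched, below 0) than at 0 nM, by hours of exposure and cisplatin dose. The counts rose from 2 genes at 2 h to 5819 at 15000 nM and 24 h.

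At 6 h and 15000 nM cyclin E and stress genes were already higher and the mitotic genes lower. ATF3 rose by 0.70 ± 0.43 (SD, n = 56; limma adjusted p = 1.39e-15) in 54 of 56 lines, CCNE2 by 0.48 ± 0.26, CDKN1A by 0.46 and CCNE1 by 0.42. PMAIP1 rose by 0.46, RSRP1 by 0.46, TNFSF9, a ligand of the TNF family, by 0.45, RGS2, a regulator of G protein signalling, by 0.44, and the homeobox and zinc finger factors MSX1 and OSR2 by 0.38 and 0.39. ATXN1 fell by 0.75 ± 0.49 (limma adjusted p = 4.57e-15) and was lower in 50 of 56 lines. JARID2, a component of the Polycomb repressive complex, and ZMIZ1 each fell by 0.65 and were lower in 55 of 56 lines. NAV2, PSD3, ROR1 and PSRC1 were lower at -0.60, -0.54, -0.53 and -0.53, CUX1 and FNDC3B at -0.52, and TCF7L2, a transcription factor of Wnt signalling, at -0.51. FNDC3B was lower in 56 of 56 lines.

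All 25 mitotic genes fell at 15000 nM and 6 h, also when adjusted over the list alone, with CENPE at -0.49, PLK1 at -0.43, CENPA at -0.42 and AURKA at -0.36. Of the S phase genes 20 of 25 rose and 0 fell, or 21 and 0 when adjusted over the list alone, including CDC6 at 0.31. The p53 targets had 14 of 22 members higher and 0 lower, or 15 and 0 when adjusted over the list alone, with PLK3 and GADD45A at 0.33. Immediate early genes had 10 of 17 higher and 1 lower, or 11 and 1 when adjusted over the list alone, with KLF4 at 0.30 and IER5 at 0.28. In the ATF4 and unfolded protein response list 11 of 17 rose, or 12 when adjusted over the list alone, led by DNAJB9 at 0.33. Of 11 cholesterol synthesis genes 5 rose and 0 fell, or 6 and 0 when adjusted over the list alone, with IDI1 at 0.13 and INSIG1 at 0.12. The histone list was not called (camera adjusted p = 0.486), with H1-2 at -0.14.

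At 15000 nM and 6 h 2725 genes changed, 1422 higher and 1303 lower, and 11 by at least 0.5. Camera called 11 lists. The 6 that held with an estimated correlation were mitotic genes (adjusted p = 0.000236), S phase genes (0.00232), the ATF4 list (0.00799), immediate early genes (0.0226), p53 targets (0.0284) and cholesterol synthesis (0.0284). Without the cell line as a block limma called 0 genes, with 285 at unadjusted p below 0.05 against 3799 with it, and 1616 passed with all arrays in 1 fit. In 3 lines more than 100 genes moved by more than 1 from the 0 nM array at both doses after 6 h, against medians of 18.5 genes at 15000 nM and 6.5 at 3000 nM. These were OVCAR-3 (421 and 373), A549 (109 and 121) and T-47D (119 and 116), whose treated arrays differed from each other in only 25, 10 and 3 genes. Their 0 nM arrays may stand apart, or both doses may act alike in these lines, which was not tested. Without these 3 lines, left out after the data were seen, 2869 genes changed at 15000 nM and 131 at 3000 nM, and the 11 lists called at 15000 nM and the 6 called at 3000 nM kept their call.

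The calls of 5 further lists at 15000 nM and 6 h were lost with an estimated correlation, with the same counts when adjusted over each list alone. Of 11 platinum and copper transport genes 4 fell and 0 rose, with ABCC1 at -0.30 in 55 of 56 lines (adjusted p = 0.0505 with an estimated correlation). Of 16 NRF2 targets, which respond to oxidative stress, 6 rose and 1 fell, with OSGIN1 at 0.30 and HMOX1 at 0.27 (adjusted p = 0.0822 with an estimated correlation). Of 16 interferon-stimulated genes 6 rose, with IRF1 at 0.28 (adjusted p = 0.102 with an estimated correlation). Of 9 heat shock genes 4 rose, with the cochaperones DNAJB1 and BAG3 at 0.20 and 0.14, and of 10 ribosome biogenesis genes 4 rose, with NOP16 at 0.12 (adjusted p = 0.12 for each with an estimated correlation).

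At 3000 nM and 6 h a small set of cell-cycle genes moved. BORA, an activator of mitotic kinases, and PSRC1, a spindle protein gene, each fell by 0.23 (SD 0.20, n = 56; limma adjusted p = 9.16e-09) in 52 and 51 of 56 lines, PLK1 fell by 0.21, and CCNE2, OSR2 and ORC1 rose by 0.19, 0.17 and 0.15. Of 25 mitotic genes 20 fell and 0 rose, or 24 and 0 when adjusted over the list alone. Of 25 S phase genes 4 rose, or 11 when adjusted over the list alone, and of 22 p53 targets 5 rose, or 11 when adjusted over the list alone, with CDKN1A at 0.19 and PPM1D at 0.14. In all 135 genes changed, 60 higher and 75 lower. With each array's median subtracted they were 249, 39 higher and 210 lower, and without the melanoma lines 80. Limma called 0 genes without the block and 0 with all arrays in 1 fit, with 26 and 483 at unadjusted p below 0.05 against 1286 within lines.

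Camera called 6 lists at 3000 nM and 6 h. With an estimated correlation mitotic genes held at adjusted p = 3.06e-07, p53 targets at 0.00229, S phase genes at 0.00850 and the ATF4 list at 0.0256. In the ATF4 list 1 of 17 rose, DDIT4 at 0.17, or 4 when adjusted over the list alone. Of the immediate early genes ATF3 rose by 0.15, or 2 rose and 1 fell when adjusted over the list alone, and of the 16 interferon-stimulated genes 0 passed either way, 0.09 for IRF1 being the change nearest the threshold. These last lists lost their call, each at adjusted p = 0.12 with an estimated correlation.

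After 2 h few genes moved at either dose, all of them lower. At 15000 nM PDIA3, a chaperone of the endoplasmic reticulum, fell by 0.14 ± 0.21 (SD, n = 55) and TOP2A, the mitotic topoisomerase, by 0.13 ± 0.20 (limma adjusted p = 0.0428 each), lower in 42 and 41 of 55 lines. At 3000 nM the kinase AURKA fell by 0.09 ± 0.12 and CDC20 fell by 0.08 ± 0.11 (SD, n = 54; limma adjusted p = 0.0288 and 0.0294), lower in 41 and 42 of 54 lines. The mitotic list was nevertheless called at both doses, with 12 of 25 members lower when adjusted over the list alone at each dose (camera adjusted p = 1.13e-17 and 6.49e-14, and 1.82e-05 and 0.000835 with an estimated correlation). Both doses were compared with the same 0 nM arrays, so the calls of the mitotic list at the 2 doses are not independent. Camera called no other list, and fry also called the 6 melanocyte markers higher at 15000 nM (adjusted p = 0.0498). Changes of CDKN1A at 15000 nM, 0.09, and FAS at 3000 nM, 0.10, did not pass. At unadjusted p below 0.05 there were 1200 and 978 genes. Over the alternative settings the count of 2 genes ranged from 0 to 5 at 15000 nM and from 0 to 4 at 3000 nM, and where limma called 0 genes, between 24 and 1801 passed at unadjusted p.

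**Figure D3:**
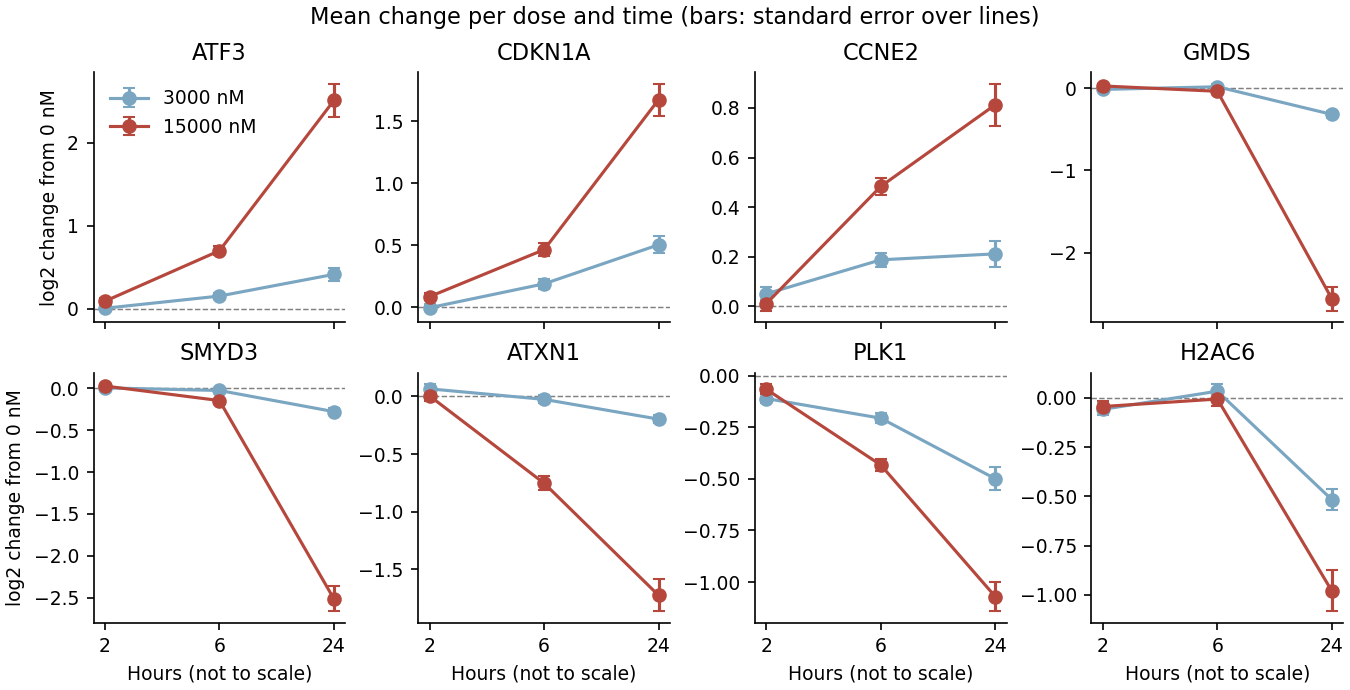
Points give the mean log2 change from 0 nM for 8 genes at 2, 6 and 24 h (categories, not to scale) at 3000 and 15000 nM, with standard errors over lines as bars. ATF3 reached 2.51 and GMDS -2.56 at 15000 nM and 24 h, where GMDS had been -0.04 at 6 h.

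The dose difference itself was tested within lines. At 24 h the 15000 nM arrays exceeded the 3000 nM arrays by 2.09 ± 1.28 (SD, n = 55) for ATF3, 1.42 for CXCL8 and 1.17 for CDKN1A, and lay below them by -2.25 for GMDS, -2.25 for SMYD3 and -2.13 for VPS13B. Here 20 of 22 p53 targets and 15 of 17 immediate early genes were higher, 17 of 25 mitotic genes were lower, and of the histone genes 2 were higher and 1 lower. Adjusted over the list alone the counts were 20, 16, 17, 0 and 1. Camera called p53 targets (adjusted p = 2.18e-09), immediate early genes (8.95e-09) and mitotic genes (1.37e-06), calls lost at adjusted p = 0.144, 0.126 and 0.378 with an estimated correlation, and not histone genes (adjusted p = 0.946). At 6 h the difference was 0.55 for ATF3, 0.39 for RGS2 and 0.35 for RSRP1, and -0.73, -0.58 and -0.57 for ATXN1, ZMIZ1 and JARID2. At 2 h DDIT4, an inhibitor of the mTORC1 kinase, was higher by 0.20 ± 0.22 (SD, n = 54; limma adjusted p = 0.000168) in 44 of 54 lines, PAIP2B by 0.16 and GABRD by 0.14, and DENND4A and RALGAPA1 were lower at -0.25 and -0.13. The counts were 5560 at 24 h, 3066 higher and 2494 lower, 2624 at 6 h, 1272 higher and 1352 lower, and 11 at 2 h, 6 higher and 5 lower. Subtracting array medians gave 3897 and 2034 at 24 h, 2485 and 1010 at 6 h, and 10 and 3 at 2 h. Without the block limma called 622 genes at 24 h, 0 at 6 h and 0 at 2 h, with 168 and 64 at unadjusted p below 0.05 at 6 and 2 h against 3759 and 1972 within lines.

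The change at 15000 nM differed between times. Between 6 and 24 h the change increased by 1.83 ± 1.57 (SD, n = 55) for ATF3, 1.63 for CXCL8 and 1.21 for CDKN1A and decreased by 2.51 ± 1.13 for GMDS, with -2.38 for SMYD3 and -2.07 for DPYD. The NF-kB targets were 14 of 16 higher, or 15 when adjusted over the list alone, and cholesterol synthesis genes 6 of 11 lower, also when adjusted over the list alone, where INSIG1 had risen at 6 h. Camera called both (adjusted p = 9.37e-07 and 1.23e-05), which with an estimated correlation became adjusted p = 0.095 and adjusted p = 0.104. Between 2 and 6 h the change increased by 0.60 for ATF3, 0.47 for CCNE2 and 0.43 for PMAIP1 and decreased by 0.75 for ATXN1, with -0.60 for NAV2 and ZMIZ1. There were 4311 genes between 6 and 24 h, 2396 up and 1915 down, and 1152 between 2 and 6 h, 567 up and 585 down. Without the block limma called 107 and 0, the latter with 89 at unadjusted p below 0.05 against 2469 within lines.

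The 0 nM arrays also changed between 2 and 24 h. DDIT4 rose by 1.27 ± 0.87 (SD, n = 55; limma adjusted p = 3.97e-14), ZNF322 by 0.97 and FAM200C by 0.88, while ATF3 fell by 1.16 ± 0.77 (limma adjusted p = 1.6e-14) in 53 of 55 lines, with CCN2, which encodes a matrix protein, at -1.11 and MAFF at -1.09. Of 17 immediate early genes 10 fell and 0 rose, or 14 and 1 when adjusted over the list alone. Of 16 NF-kB targets 8 fell, or 13 when adjusted over the list alone, with CXCL8 at -0.81. Cholesterol synthesis genes rose in 10 of 11 cases, or 11 when adjusted over the list alone, with INSIG1 at 0.44, and 18 of 25 mitotic genes rose, also when adjusted over the list alone, with KIF20A at 0.46. Camera called these lists at adjusted p = 3.9e-07, 5.41e-06, 7.23e-06 and 2.98e-05, and none held with an estimated correlation, at adjusted p = 0.193, 0.129, 0.193 and 0.665. In all 3638 genes changed, 2239 higher and 1399 lower. Subtracting array medians gave 1375 and 3620, and without the block 58 genes passed.

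The changes of p53 targets and mitotic genes varied widely between lines. They are means over gene lists, and the TP53 status of the lines was not used. At 15000 nM and 24 h the p53 target change averaged 0.70 ± 0.57 (SD, n = 55) and ran from 0.01 in the colon line HCC-2998 to 2.63 in the lung line NCI-H460. The mitotic gene change averaged -0.35 ± 0.33 and ran from -1.50 in the melanoma line LOX to 0.20 in the CNS line SNB-75. No difference between tissues was found for either (permutation of tissue labels, adjusted p = 0.642 and 0.751 over 22 lists). The number of genes that moved by more than 1 was 1 in HCC-2998, 338 in the median line and 1276 in OVCAR-3. The treated OVCAR-3 array stood apart in RNA integrity, with a change of 5.19 in the ACTB 3' to 5' difference, where no other line exceeded 0.52, and of 1.76 in that of GAPDH. The number ran from 1 to 282 genes in the 7 colon lines and from 364 to 1207 in the 5 CNS lines (permutation of tissue labels on ranks, p = 0.0129, a test chosen after the data were seen). The ACTB change moved the same way, averaging 0.01 ± 0.03 (SD, n = 7) in colon and 0.28 ± 0.19 (SD, n = 5) in CNS lines, although over all tissues its difference did not pass (permutation p = 0.178). With it as covariate and without OVCAR-3 the tissue difference in the number of genes did not pass either (permutation p = 0.142, against 0.0142 without OVCAR-3 alone). Without HCC-2998 or OVCAR-3, left out after the data were seen, no count at 15000 nM and 24 h moved by 1.5 times.

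**Figure D4:**
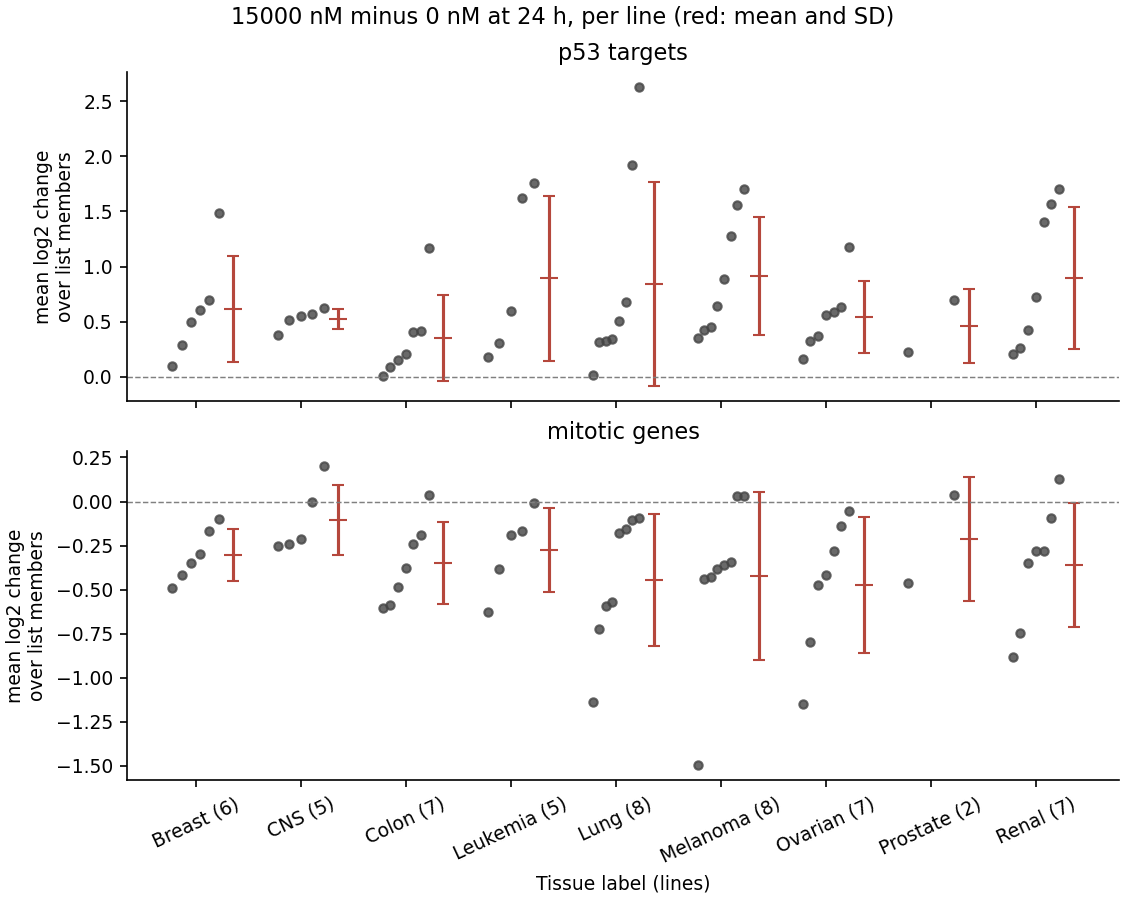
Each point is the mean log2 change of p53 targets or mitotic genes in 1 line at 15000 nM minus 0 nM after 24 h, by tissue label, with mean and SD in red. Lung lines spanned 0.02 to 2.63 for p53 targets and leukemia lines 0.18 to 1.76.

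Some other groups of genes differed between tissues in their change. Ribosome biogenesis genes averaged -0.40 ± 0.10 (SD, n = 5) in leukemia lines and 0.33 ± 0.12 (SD, n = 5) in CNS lines (permutation adjusted p = 0.00022). Melanocyte markers averaged -0.39 ± 0.29 (SD, n = 8) in melanoma lines and between -0.10 and 0.07 elsewhere (permutation adjusted p = 0.00407). Their level at 0 nM and 24 h was 10.08 in melanoma lines and 4.80 or less in other tissues. Lines of other tissues therefore had little signal in which a fall could be seen. The difference in change cannot be told apart from where these genes are expressed. Platinum and copper transport genes averaged -0.34 in CNS lines and 0.02 in colon lines (permutation adjusted p = 0.0114), and mesenchymal markers -0.33 in CNS and 0.10 in leukemia lines (permutation adjusted p = 0.0457). With the ACTB change as covariate and without OVCAR-3, which was tried after the data were seen, ribosome biogenesis genes and melanocyte markers still differed between tissues (permutation adjusted p = 0.00022 and 0.0055), while transport genes and mesenchymal markers no longer passed (permutation adjusted p = 0.052 each, against 0.00535 and 0.0338 without OVCAR-3 alone). The 5 genes with the smallest p in the moderated F test across tissues had their lowest mean change in the tissue where their 0 nM level was highest, although single tissues were not tested. NLGN1, a synaptic adhesion gene, changed by -3.82 ± 1.08 in melanoma and -2.68 ± 1.07 in CNS lines and by 0.08 ± 0.20 in colon lines (limma adjusted p = 6.4e-08). CPN1, ST8SIA1 and CHL1 changed by -1.02, -1.42 and -1.93 in melanoma lines, and MYLK, a myosin kinase gene, by -2.34 in CNS and -1.56 in ovarian lines. Their 0 nM levels at 2 h were highest in melanoma (NLGN1 7.87, CPN1 7.64, ST8SIA1 6.20) and, for MYLK, in CNS lines (10.31). In all 1008 genes differed between tissues, 642 of which also passed with the ACTB change as covariate and without OVCAR-3. The count was 590 without NCI-ADR-RES, MDA-MB-435 and SNB-19, which are reported to share an origin with other lines of the panel. The list scores were not retested without these lines, and the permutations of tissue labels took them as independent.

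Leukemia lines responded differently from the other lines in 518 genes, 209 higher and 309 lower. RABGAP1L changed by 0.18 ± 0.58 (SD, n = 5) in leukemia lines and by -1.30 ± 0.75 (SD, n = 50) in the others (limma adjusted p = 0.00457). ID1, an inhibitor of differentiation factors, changed by 0.91 ± 1.68 (SD) against -0.56 ± 0.58, and IER3 by 1.77 ± 1.19 against 0.29 ± 0.64. POLR1G, a subunit of RNA polymerase I, changed by -0.94 ± 0.19 against 0.14 ± 0.49. UTP25, which acts in ribosome assembly, changed by -0.82 ± 0.71 against 0.24 ± 0.33, and ATP8A1 by -1.37 ± 0.84 against -0.23 ± 0.55. The limma fit takes a common spread for both groups, so p may be too small for genes that vary more among the 5 leukemia lines. With array medians subtracted the split was 125 and 682. Without HL-60 the count was 138, and without MOLT-4 333.

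The relation between p53 and mitotic changes across lines was taken within clusters, because the lines fell into separate groups. A mixture model favoured 2 clusters of the p53 target change (BIC -76.55 against -102.17 for 1), one of 42 lines from 0.01 to 0.89 and one of 13 lines from 1.17 to 2.63. The mitotic change averaged -0.29 ± 0.26 (SD) in the 42 lines and -0.56 ± 0.44 (SD) in the 13, a difference that was not tested. The clusters were cut on the p53 change, which narrows its range inside each. Within them the p53 change correlated with the mitotic change at r = 0.201 (permutation p = 0.2, adjusted 0.429; rho = 0.293, p = 0.0594, adjusted 0.178) and r = -0.370 (permutation p = 0.214, adjusted 0.429; rho = -0.407, p = 0.169, adjusted 0.338), over 6 relations. Without the 2 lines farthest from the median r was 0.336 (permutation p = 0.0335, not adjusted) and -0.431 (0.188). Within tissues of at least 6 lines r was negative in 5 of 6, at -0.589 in breast, -0.013 in colon, -0.633 in lung, -0.557 in melanoma and -0.524 in renal lines, and 0.303 in ovarian lines. These values take all lines of a tissue, from both clusters, and so do not bear on the 42 lines alone. At 3000 nM the clusters held 48 and 8 lines with r = -0.0507 (permutation p = 0.734; rho = -0.101, p = 0.491) and r = 0.120 (exact permutation p = 0.794; rho = 0.0952, p = 0.84), and without 2 lines -0.0256 and -0.469.

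The p53 target level at 0 nM and 2 h was set against the later change in the same way. Within the cluster of 41 lines r was 0.369 (permutation p = 0.0176, adjusted 0.106; rho = 0.361, p = 0.0212, adjusted 0.127), and in the 13 lines r was -0.0434 (permutation p = 0.881; rho = -0.192, p = 0.53). Neither relation passed after adjustment. Without the 2 lines farthest from the median r was 0.454 (permutation p = 0.00359, not adjusted) and 0.159 (0.674), so the larger cluster had a smaller p and the sign in the smaller cluster rested on those lines. Within tissues r ran from 0.398 in lung to 0.916 in colon lines, over all lines of a tissue and so over both clusters, and does not bear on the relation within a cluster. The clusters were defined on the change itself, which narrows its range within a cluster and can weaken r. Giving the relation within them, in place of the pooled value that was planned and is not given here, was chosen after the data were seen.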

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

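The comparison of immediate early genes with the 0 nM arrays at 2 h, the fit of their mean rise with the ACTB ratio, the permutations of tissue labels without the leukemia lines and with the ACTB ratio, and the list of other very large genes were chosen after the results they bear on had been seen; the other tests of this part were written down before their outcome was known. All 14 counts of genes were set against 100 splits, made by flipping the signs of the lines' changes or by permuting tissue labels, the real one included.

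A first pattern was the deep fall of genes of unrelated function at 15000 nM and 24 h, such as GMDS, DPYD, VPS13B and WWOX, with 356 genes lower by at least 0.5. These genes are known for very long transcription units, so a list of 64 genes held to be very large was made, of which 42 were measured and not already named; gene lengths were not given and were not checked. The median change of these 42 was -0.14 at 15000 nM and 24 h, -0.03 at 3000 nM and 24 h and -0.05 at 15000 nM and 6 h, at percentile 0 of 10000 random lists of matched level each time, where the lowest random medians were -0.05, -0.02 and -0.03. A low level on the arrays is argued against, since the 9 members brighter than the median gene had a median of -1.13, again at percentile 0. Loss of RNA integrity, as far as the ACTB ratio measures it, is argued against by 97.47 percent of the falls (347 of 356). These kept limma adjusted p under 0.05 and at least 50 percent of their size with that ratio as covariate and without OVCAR-3. The 356 are all falls of at least 0.5, not only those of very large genes, and a ratio from a single gene may correct too little. A block of transcript elongation by platinum adducts, which longer genes would meet more often, may underlie the pattern as a hypothesis. Lengths of all genes, or nascent RNA along each gene, would test it, and neither was given. Faster decay of particular transcripts stays open and was not tested.

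A second pattern was the 1008 genes whose 24 h change differed between tissues. Among 6563 genes whose tissue means at 0 nM spanned less than 1 on the log2 scale, 276 passed, so the differences were not confined to unevenly expressed genes. Expression in few tissues was not tested by this count, because these genes were selected for even expression, and the count was not set against permuted labels. For the 660 unevenly expressed genes expression in few tissues cannot be told apart from other causes. Their largest change was in the tissue with the highest level in 198 of them, or 30 percent, between the bounds set beforehand of 15 and 33 percent. A response of the leukemia lines alone is argued against, since 436 genes passed without them over 50 lines, and of 100 permutations of the tissue labels of those lines only 1, the real one, gave as many (highest other 5). The count of 436 lay between the bounds of 100 and 500 written beforehand, which had not been set against chance. Loss of RNA integrity, as far as the ACTB ratio measures it, is argued against as the whole cause. With that ratio as covariate and without OVCAR-3 697 genes passed over 54 lines, and of 100 permutations of the tissue labels only 1, the real one, gave as many (highest other 31). It stays open for part of the genes, because 642 of the 1008, or 63.69 percent, kept their call, between the bounds of 50 and 80 percent, against 918 without OVCAR-3 alone. Tissue itself, the biological difference named by the labels, could account for the remainder and was not separated from other properties of the lines.

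A further pattern was the rise of 15 immediate early genes at 15000 nM and 24 h, a time by which 10 of 17 had fallen at 0 nM. A fall with time that both arms share cancels against the 0 nM arrays of 24 h, so it cannot alone produce these rises. Whether a gene rose above its 2 h level or only failed to fall is a separate question. Of the 15 genes 9 (60 percent) lay above the 0 nM arrays of 2 h, between the bounds of 50 and 80 percent, which does not decide it. ATF3 was 1.33 above them (limma adjusted p = 2.74e-08), whereas MAFF differed by 0.14 (limma adjusted p = 0.392). Loss of RNA integrity, as far as the ACTB ratio measures it, is argued against as the whole cause. With the ACTB ratio as covariate and without OVCAR-3, 12 of 15 (80 percent) kept their rise, which just met the bound of at least 80 percent written beforehand, and ATF3 was at 2.06, DUSP1 at 0.85, KLF4 at 0.81 and JUNB at 0.64. The mean rise of the 15 genes was 0.76 ± 0.08 (SE, n = 54) before and 0.63 ± 0.09 (SE) after this correction, or 82.4 percent of it. For EGR1, IER3 and KLF6, which did not keep their call (0.42, 0.32 and 0.06, adjusted p = 0.128, 0.051 and 0.639), this stays open. For the genes that did not lie above the 0 nM arrays of 2 h, a new rise and a fall held back were not separated.

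Chance can be excluded for the counts against 0 nM at 24 and 6 h. At 15000 nM and 24 h, 1 split, the real one, gave as many as 5819 genes and the highest other gave 1. For 3000 nM and 24 h the values were 1298 and 1, for 15000 nM and 6 h 2725 and 126, and for 3000 nM and 6 h 135 and 2. At 2 h the real count of 2 at 15000 nM only equalled the highest other of 2, which 2 of 100 splits reached, and the real count of 2 at 3000 nM exceeded the highest other of 1. The share of splits met the bound written beforehand at both doses. Other splits gave any gene in only 3 cases at 15000 nM and 5 at 3000 nM, so this share mostly reflects the threshold. As the 15000 nM count was 0 in most alternative settings, chance is not excluded for the counts of 2 at 2 h. Chance can be excluded for the dose differences, at 5560 against 1 at 24 h, 2624 against 13 at 6 h and 11 against 2 at 2 h, and for the 0 nM arrays between 2 and 24 h at 3638 against 6.

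The effect of 15000 nM differed between times in 4311 genes from 6 to 24 h (highest other split 0) and in 1152 from 2 to 6 h (highest other split 2), and chance can be excluded for both. It differed between tissues in 1008 genes (highest other split 20) and between leukemia and other lines in 518 (highest other split 42). Chance can also be excluded for these if the lines are taken as independent. The permutations were not repeated without the lines reported to share an origin. Tissue differences of list scores had permutation adjusted p = 0.00022 for ribosome biogenesis, 0.00407 for melanocyte markers, 0.0114 for platinum and copper transport and 0.0457 for mesenchymal markers, as given with their means in the results, the latter pair not passing with the ACTB ratio as covariate. A pair of lines stood apart from their tissue, where such a test marks about 1 in 20 groups by chance and 16 groups were tested. HCT-116 had a p53 target change of 1.17 among colon lines, next to 0.41, and LOX a mitotic change of -1.50 among melanoma lines, next to -0.44. The ACTB 3' to 5' difference, which lies outside the gene comparisons, was 0.21 higher at 15000 nM than at 0 nM after 24 h.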

How the results depend on the processing

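Analyses without HCC-2998, OVCAR-3, MALME-3M, A549 or T-47D were chosen after the data were seen. Of the main values and counts recomputed under the alternatives, 241 kept their call or stayed within 1.5 times, 12 became larger, 55 smaller and 2 turned; of single named genes 7221 kept their side of the threshold, 606 lost their call, 18 gained one and 5 turned. Except where a reason is given, the cause was not tested.

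Without the cell line as a block the difference between lines entered the spread, by construction, and limma counted 1056 genes at 15000 nM and 24 h, 622 between the doses at 24 h, 107 between 6 and 24 h and 58 in the 0 nM arrays. Counts of 0 without the block were those of 3000 nM and 24 h, both doses at 6 h, both at 2 h, the dose difference at 6 and at 2 h and the change from 2 to 6 h, with between 24 and 285 genes at unadjusted p below 0.05. The called lists went from 44 to 28, and from 44 to 18 with an estimated correlation. Fry, which does not compare a list with other genes, kept all camera calls in the same direction. With all arrays in 1 fit the counts were 316 at 3000 nM and 24 h, 1616 at 15000 nM and 6 h, 1048 for the dose difference at 6 h, and 0 at 3000 nM and 6 h and for each comparison at 2 h, with between 283 and 1060 at unadjusted p. Testing all probe sets, which are more than the genes, gave 8738 at 15000 nM and 24 h.

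Array-median subtraction gave 249 genes at 3000 nM and 6 h and 807 for leukemia lines. Without melanoma lines 80 passed at 3000 nM and 6 h. Without NCI-ADR-RES, MDA-MB-435 and SNB-19 the tissue count was 590. Leaving out 1 leukemia line gave between 138 (without HL-60) and 602 (without RPMI-8226) genes, and 333 without MOLT-4. OVCAR-3, A549 and T-47D differed from their 0 nM arrays in many genes at both doses after 6 h. Without these lines 2869 genes passed at 15000 nM and 6 h and 131 at 3000 nM and 6 h, and without OVCAR-3 alone 2773 and 134. Splitting the 0 nM lines, which leaves fewer lines per dose, gave 340 genes shared by the doses.

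The counts of 2 at 2 h had little margin. At 15000 nM the count was 0 with array medians subtracted, all probe sets, only lines with all 9 arrays, or without the breast, CNS, colon, leukemia, melanoma, prostate or renal lines, with between 881 and 1801 at unadjusted p. It was 1 without lung or ovarian lines, 4 with bright genes or the mean of probe sets, and 5 by the Wilcoxon test. At 3000 nM it was 0 with all probe sets, without the lines of shared origin, or without CNS, colon, lung or ovarian lines, with between 739 and 1506 at unadjusted p. It was 1 with array medians subtracted, the mean of probe sets or without renal lines, and 4 with bright genes, only lines with all 9 arrays or the Wilcoxon test. The 11 genes of the dose difference at 2 h became 4 with quantile normalization, 5 with all probe sets, 2 without CNS or ovarian lines, 4 without breast, 5 without melanoma, 6 without leukemia and 7 without renal lines, and 31 by the Wilcoxon test.

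Values that turned sign were those of genes near 0: PTPRC at 15000 nM and 2 h (-0.0107), and LSS (0.0167) and CDH1 (0.0272) at 3000 nM and 2 h with the mean of probe sets, CXCL8 at 3000 nM and 2 h without the block (-0.0051), and SOX10 in the 0 nM arrays without melanoma lines (-0.0173). In the 42 lines of smaller p53 change, r between the p53 and mitotic changes was 0.201 (permutation p = 0.201) and became 0.327 (p = 0.0346) with array medians subtracted and 0.336 (p = 0.0335) without the 2 lines farthest from the median, p-values that are not adjusted. In the 41 lines with an earlier p53 level, r with that level went from 0.369 (p = 0.0167) to 0.454 (p = 0.00359) without the 2 farthest lines. In the 13 lines of larger p53 change, r with the earlier p53 level turned to 0.0536 with the median over members and 0.159 without the 2 farthest lines. Dim genes have little signal over background, which limits how small a fall can be seen in them.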

Other observations

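The list of other very large genes was chosen after the largest falls had been seen, and the values of this part belong to no planned comparison. Genes with very long transcription units, apart from those already named, were lower as a group after cisplatin. At 15000 nM and 24 h 23 of 42 fell and 0 rose, also when adjusted over the list alone. PTPRG, a receptor tyrosine phosphatase, fell by 1.71 in 51 of 55 lines, CDKAL1, a tRNA-modifying enzyme, fell by 1.51 in 54, and FTO, an RNA demethylase, fell by 1.40 in 55 (limma adjusted p = 1.19e-13, 6.49e-16 and 4.11e-15). RAD51B, a recombination gene, fell by 0.82 in 55 of 55 lines (limma adjusted p = 6.98e-18), and ROBO1, an axon guidance receptor, fell by 1.13 in 50 (limma adjusted p = 1.53e-10). At 3000 nM and 24 h 9 fell and 0 rose, or 10 and 0 when adjusted over the list alone, and at 15000 nM and 6 h 13 and 0, or 14 and 0.

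The number of genes moved differed widely between lines. At 15000 nM and 24 h the lines with the fewest genes moved by more than 1 on the log2 scale were HCC-2998 with 1, MDA-MB-231 with 26 and A498 with 43, and those with the most were OVCAR-3 with 1276, SF-295 with 1207 and MALME-3M with 1165. The treated OVCAR-3 array also had by far the largest change of the ACTB 3' to 5' difference, 5.19, and of that of GAPDH, 1.76, and its count is to be read with that in mind. Labelling controls were lower at 3000 nM than at 0 nM after 24 h by a mean difference of -0.12 ± 0.26 (SD, n = 56) and higher in 20 of 56 lines (sign-flip permutation p = 0.00039, adjusted 0.00468 over 24 tests).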
